A study of Gossypium hirsutum with 2 samples.

How the data were processed

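The study hybridised leaf RNA of Upland cotton to the Affymetrix cotton array. Per the labels, biotin-labelled cRNA was made from 5.0 µg total RNA, and leaves came from 3 field plots per treatment. The material used here is 1 array for well-watered and 1 array for drought-stressed leaves, assigned to groups by the sample titles. The deposited intensity values are linear MAS5 signals computed with GCOS and MAS5, per the submitters' processing notes, and software versions are not given in the sources used here. From the values, both arrays had been scaled to a single trimmed mean, which is judged from the numbers and not stated. A smaller deposited list gives signal, detection call and detection p-value for 110 probe sets, per the file headers. This deposited p-value concerns detection of 1 probe set on 1 array, not a difference between the arrays. The signals in the list are close to those of the value table but not equal to them, and how the list was made is not given in the sources used here.

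The main quantity was log2(drought signal) minus log2(well-watered signal), with the values as deposited and no pseudocount. Control probe sets (155: 103 spike-in and internal controls and 52 reporters) were left out. A probe set was called measurable when its mean log2 signal reached the median over plant probe sets, which corresponds to a signal of 72.3 and keeps 11989. Differences were counted at 2-fold or more. No test was run, because 1 array per group leaves no replicate error. Exact binomial intervals for counts and order-statistic 95% intervals for list medians describe probe sets, which are not replicates. Precision was described from pairs of measurable probe sets of 1 transcript cluster, taking the 2 brightest. Such pairs can also differ because they detect different transcripts, and their IDs can mark opposite orientations (A or S), which the pairing ignored. A list with at least 5 measurable members received a median and its percentile among 10000 random lists matched in 20 classes of mean signal. The self-test put known differences into simulated values for this comparison over 11989 probe sets. Of 100 probe sets changed 2-fold, 45 were called, and of 100 changed 4-fold, 99 were called, while 300 of 11789 unchanged probe sets were called. With 1 array per group, the simulated noise could not be taken from replicates. These counts therefore check the calculation and are not false-call or recovery rates of the experiment. Of 100 lists of 12 shifted by 0.5 on the log2 scale, 99 lay above the upper tail bound, and of 100 unshifted lists 2 lay outside either bound. Median intervals held the true value in 989 of 1000 draws.

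Gene names came from the platform annotation joined by gene identifier to a gene table of the assembly Gossypium_hirsutum_v2.1. A single gene was given for 697 probe sets, several for 46, and none for 23234, and all 697 were found in the gene table. An alias other than a locus number was present for 324, of which 200 were measurable, from 171 genes. Coordinates of that assembly were not used, and probe sets with several genes were not named. Homoeologous and paralogous copies share probes, above all in probe sets ending in _s_at or _x_at, so a name can stand for more than 1 copy. The species a probe set was designed from was read from the start of its ID (Ghi for Gossypium hirsutum, Gra for Gossypium raimondii), by the array's naming convention.

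The rule for named genes was fixed before the data were examined. It took the 10 largest positive and 10 largest negative log2 differences among measurable probe sets with a gene name, using 1 probe set per gene (the brightest) and leaving out those ending in _x_at. It also took up to 4 members of each of the 31 gene lists by size of difference, and up to 5 named increases and 5 named decreases from the deposited list. After the values were seen, a gene name was read as an alias other than a locus number, since no descriptions were used. The 17 gene families grouped by alias, the bright genes and the unnamed loci were likewise chosen after the values were seen; every measurable member of a family was kept in its count.

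Alternatives fixed in advance were centring on the median, quantile normalization, intensity-dependent centring with a lowess span of 0.3, no filter, a filter at the 75th percentile of mean signal, a filter on both arrays, a pseudocount at the 25th percentile of all signals (26.4), leaving out probe sets ending in _x_at or _s_at, keeping probe sets designed from Gossypium hirsutum, and thresholds of 1.5-fold and 3-fold. For gene lists, 1 probe set per gene and leaving out members of the deposited list were also run. Scaling to the 27 hybridisation spike-in probe sets was added after seeing the data. A pair of filters on reporter controls was added then too. The earlier one kept signals above every reporter but the brightest on at least 1 array; its limits of 107 and 186 differ between the arrays and so favour a direction, and after its counts were seen a filter on mean signal was added, with both reported. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.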

Results

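Leaf transcript levels were compared between well-watered and drought-stressed field plants of Upland cotton (Gossypium hirsutum), of an Acala cultivar that the labels call drought tolerant. The labels describe leaves in the third topmost position collected 9 days after water was withheld, with 8 plants to a replicate and 3 field plots per treatment. They give the age of the plants as 9 weeks, which is longer than the time between the planting and harvest dates in the same labels. The values analysed are MAS5 signals, the linear probe-set intensities of Affymetrix software, from 2 cotton arrays, 1 for well-watered and 1 for drought-stressed leaves. Whether the RNA of the plots was pooled on these arrays is not stated. With 1 array per group there is no replicate error, so no p-value is given, and every difference below describes these 2 arrays. Each array held 24132 probe sets, of which 23977 represent plant transcripts. The median plant signal was 75.6 on the well-watered array and 78.3 on the drought array, and the mean after trimming 2% from each end was 250.09 on both. Among the control probe sets for 3 plant transcripts, the ratio of 3-prime to 5-prime signal for actin was 14.1 on the well-watered array and 4.09 on the drought array. That of the ubq11 control went the other way, from 5.80 to 10.2, and that of ss1 was 1.83 and 1.30. The actin 5-prime signal was dim on the well-watered array (42.8), so 14.1 is imprecise. Such ratios follow RNA quality, and the 3 controls did not rank the arrays alike. Those of actin and ubq11 were 4.09 or more on both arrays, so RNA quality is uncertain for both samples.

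The comparison asks which leaf transcripts differ in level when irrigation is withheld. Among measurable genes with a name, each taken at its brightest probe set, the largest excess in drought leaves was that of MPK3, a stress-activated mitogen-activated protein kinase, with a signal of 84.7 in well-watered and 175 in drought leaves, a log2 difference of 1.04. The 5 dimmer probe sets of MPK3, all below the measurable minimum, went both ways, from -1.08 to 1.39, and a brighter probe set of another locus with the aliases MPK3 and MPK6 gave -0.25. The largest deficit was that of Pat1, with 324 against 92.9 (log2 difference -1.80). The fibre protein gene E6 was lower in drought leaves as well, at 216 against 92.3 (log2 difference -1.23), and so was PAP1, at 455 against 197 (-1.21). A second probe set of PAP1 gave -1.04, but the IDs of this pair mark opposite orientations (A and S), so they may not read the same strand. With the signals as deposited, only these 4 of the 20 genes named by size passed 2-fold. MPK3 was under it with a pseudocount (0.86), and against spike-in controls MPK3 was under it (0.80) while cys1 and POX9 (both -1.01) passed it. The drought signals of Pat1 (92.9) and E6 (92.3) lay under the 95th percentile of the 51 dim reporter controls on that array (144), so the sizes of these deficits are imprecise.

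The other 9 genes with the largest positive differences stayed under 2-fold. They were the peroxidase gene pod7 (log2 difference 0.99), the fasciclin-like arabinogalactan protein gene FLA13 (0.77), a WRKY transcription factor gene listed as WRKY24 and WRKY71 (0.70), the calcium sensor genes CBL1 (0.69) and CBL3 (0.51), the transcription factor gene NAC4 (0.59), the annexin gene AnnGh1 (0.54), Rab7, which encodes a small GTPase of traffic to the vacuole (0.51), and BNLGHi8377 (0.48). On the negative side followed cys1 and the peroxidase gene POX9 (both -0.76), XTH1, which encodes a xyloglucan-remodelling enzyme of the cell wall (-0.68), the homeodomain transcription factor gene HOX3 and the arabinogalactan protein gene FLA11 (both -0.64), the kinase gene MPK23 (-0.63) and RHM3 of rhamnose synthesis (-0.62). Besides MPK3, NAC4 and BNLGHi8377 each had a probe set below the measurable minimum that went the opposite way (-0.41 and -2.88). The IDs of the NAC4 pair mark opposite orientations. For scale, probe sets of the same transcript cluster differed from each other with an SD per probe set of 0.48 in the dimmest, 0.40 in the middle and 0.31 in the brightest of 3 equal classes of pair signal. A cluster number can join different genes, such as ACT4 and ACT11, so this spread is not noise alone. In 60 pairs assigned to the same gene, not divided by signal, it was 0.26, against 0.40 in all cluster pairs. MPK3, pod7, FLA13, WRKY24/WRKY71, CBL1, BNLGHi8377, E6, POX9, HOX3 and MPK23 all lay in the dimmest class of measurable signal.

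**Figure D1:**
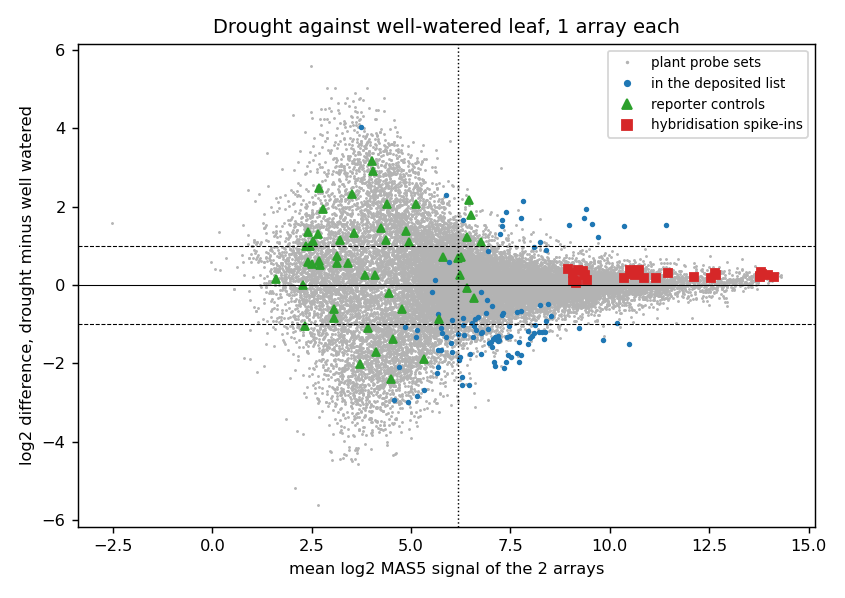
Each point is 1 probe set, with the mean log2 MAS5 signal of the 2 arrays on the horizontal axis and the log2 difference (drought minus well watered) on the vertical axis. Grey, plant probe sets; blue, probe sets in the authors' deposited list; green triangles, reporter controls; red squares, the 27 hybridisation spike-in probe sets, all above 0. The dotted vertical line is the minimum mean signal of measurable probe sets (72.3), and the dashed lines mark 2-fold. The scatter widens toward low signals.

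Probe sets of known gene families were then grouped by gene name, after the values had been seen. Differences are relative to the total signal of each array. Set against the spike-in controls instead, every value is lower by 0.25 on the log2 scale, and the families whose balance this turns are named with their counts.

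All 4 measurable genes of the calcineurin B-like calcium sensors and their SOS2 kinase had positive differences in drought leaves, but besides CBL1 and CBL3 these were 0.06 for CBL2 and 0.05 for SOS2, and against the spike-ins the latter pair were lower. Both annexin genes, which encode calcium-dependent membrane-binding proteins, were higher on either scale, AnnGh1 at 354 against 514 and Anx1 at 637 against 868 (0.45). The 6 mitogen-activated protein kinase cascade probe sets divided 3 and 3. The kinase kinase kinase gene MAPKKK itself gave -1.28 on 1 probe set (-0.98 with the pseudocount) and 0.43 on another. The IDs of this pair mark opposite orientations (A and S), so they may not read the same strand.

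Of 5 vacuolar transport probe sets, which represent 4 genes, 4 were higher in drought leaves, or 3 against the spike-ins. Their median of 0.35 lay above that of 99.2% of 10000 random lists of the same size and signal. This is 1 of 10 families given such a percentile, all formed after the values were seen, so it is a description and not a test. The vacuolar pyrophosphatase gene VP measured 2490 in well-watered and 3242 in drought leaves (log2 difference 0.38) and the sodium/proton exchanger gene NHX1 measured 268 and 341 (0.35). The probe sets of VATE, a subunit of the proton-pumping ATPase, gave 0.51 and 0.20, and DET3, another subunit, gave -0.03 and turned positive under intensity-dependent centring.

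Among cell wall genes, all 4 measurable probe sets of xyloglucan endotransglucosylase/hydrolases were lower in drought leaves on every scaling tried, from -0.68 and -0.32 for the pair of XTH1 probe sets to -0.14 for XTH3. The 10 fasciclin-like arabinogalactan protein probe sets went both ways, 7 higher and 3 lower, with a median of 0.17 (95% interval over members -0.64 to 0.77), and 4 of 10 were higher against the spike-ins. A dim probe set of FLA14 was higher by 1.28, at 57.8 against 140, while the bright probe set of that gene gave 0.32. FLA6 likewise gave -1.03 on 1 probe set and 0.20 on the other. With the pseudocount FLA14 at 0.99 and FLA6 at -0.81 were both under 2-fold.

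The 5 measurable flavonoid and lignin synthesis genes had differences below 0 in drought leaves, though CHS3 (-0.05) and CCoAMOT2 were close to level. The differences ranged from -0.58 for CCR1, the cinnamoyl-CoA reductase of lignin synthesis, through -0.48 for DFR, the dihydroflavonol reductase, and -0.30 for the chalcone synthase gene CHS2 to -0.02 for CCoAMOT2. The median of -0.30 lay above 6.38% of random lists, and under quantile or intensity-dependent centring 4 of the 5 were lower. Of 6 class III peroxidase probe sets, 4 were lower (5 against the spike-ins), with a median of -0.25 (-0.76 to 0.99) above 8.80% of random lists.

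Genes that remove reactive oxygen species lay within a narrow range, from -0.41 for the iron superoxide dismutase gene FeSOD to 0.21. CAT2, a catalase gene, measured 13608 in well-watered and 15764 in drought leaves (0.21), and the ascorbate peroxidase gene gAPX 4767 and 5517 (0.21). The 7 had a median of 0.09 (-0.41 to 0.21), with 4 higher on the main scale and 0 against the spike-ins. The brightest 200 plant probe sets, with mean signals from 7866 up, themselves had a median of 0.17, which quantile normalization removed. CAT2 is among these, as is the rubisco activase gene RCA1, at 16617 against 20148 (0.28).

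Measurable hormone genes showed small differences. In ethylene synthesis, the ACC synthase gene ACS1 gave -0.31, an ACO1 gene -0.28 and ACO3 0.03 (lower against the spike-ins), and the response factor ERF3 measured 202 on both arrays. The 5 auxin influx carrier probe sets lay between -0.27 for Aux6 and 0.29 for Aux4, with a median of -0.01 that turned positive under quantile or intensity-dependent centring.

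Transcription factors as a list fixed before the data were examined were balanced: of 11 measurable probe sets, 6 were higher and 5 lower, 0 reached 2-fold, and the median was 0.01 (95% interval over members -0.24 to 0.59), above 58.2% of random lists. Besides WRKY24/WRKY71 and NAC4, NAC7 was higher by 0.48 on its measurable probe set, while another probe set of NAC7, just below the measurable minimum at 114 against 42.5, gave -1.43. NAC2 gave -0.60 on 1 probe set and 0.01 on another of about the same signal, with IDs that mark opposite orientations. Against the spike-ins, 4 were higher and 7 lower. A wider set of 12 WRKY, NAC, MYB and DREB/CBF probe sets had 7 higher and 5 lower, or 4 and 8 against the spike-ins, with a median of 0.02, above 61.7% of random lists.

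The 13 fatty acid and very-long-chain lipid probe sets had a median of 0.04 (-0.13 to 0.18), led by 0.44 for a probe set of KCS38, a ketoacyl-CoA synthase gene, whose 3 others gave -0.09, 0.04 and 0.14; of the 13, 7 were higher on the main scale and 1 against the spike-ins. Of 3 sterol methyltransferase genes, SMT2-2 gave -0.54, SMT2-1 0.09 and SMT1 0.05, the latter pair lower against the spike-ins. The 7 tubulin probe sets had a median of 0.14 (-0.67 to 0.64), 5 higher on the main scale and 2 against the spike-ins, and ran from -0.67 for BTub3 to 0.64 for the dimmest of 3 TubA4 probe sets. All 4 elongation factor 1-alpha probe sets were higher by 0.02 to 0.22, and all 4 lower against the spike-ins.

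Of the remaining lists fixed before the data were examined, the reference genes included 4 actin probe sets, ACT4 at -0.47, ACT11 at -0.04, ACT1/ACT2/ACT5 at 0.23 and ACT7/ACT8/ACT9 at 0.23 (0 of 4 higher against the spike-ins). Ribosomal protein genes were represented by RPL44 (0.58), RPS4 (-0.57), RPL37A (-0.12) and RPS16 (-0.06). Others held a single measurable gene each. The late embryogenesis abundant gene Lea14-A measured 1364 and 1594 (0.23), a peroxidase gene of the redox list 3462 and 2924 (-0.24), the aquaporin gene NIP6.1 106 and 117 (0.15), and ARF1, an alias that auxin response factors share with ADP-ribosylation factors, 1895 and 2242 (0.24). Against the spike-ins Lea14-A, NIP6.1 and ARF1 were lower. The trichome regulator GHTTG1, the only measurable match of the lists for other leaf cell types, was higher at 341 against 447 (0.39). A single match cannot stand for a cell type. The fibre protein gene E6 (-1.23) and the homeodomain gene HOX3 (-0.64), outside these lists, were lower. Lists for cell wall expansion and cell division had probe sets but 0 measurable ones, and 20 of the 31 lists matched 0 probe sets. Lists were searched in short aliases without descriptions, so an empty list does not mean absent signal. Measurable genes missed this way include the expansin gene EXPA3D (-0.07 and -0.06), the histone genes HIS2B (0.67) and HIS3 (0.39), VP and NHX1.

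**Figure D2:**
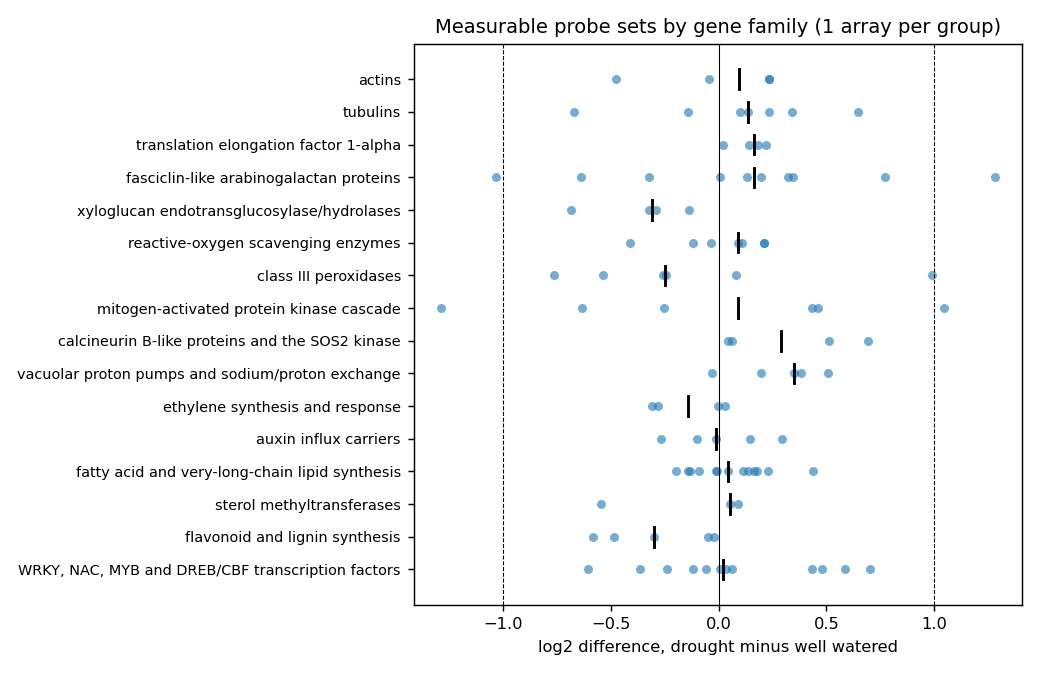
Log2 difference (drought minus well watered, horizontal axis) of each measurable probe set in the gene families with at least 3 such probe sets. Each blue point is 1 probe set from 1 array per group, black bars are family medians, and dashed lines mark 2-fold. Measurable xyloglucan endotransglucosylase/hydrolase and flavonoid and lignin probe sets lie left of 0, CCoAMOT2 at -0.02 turning positive under quantile or intensity-dependent centring, while 4 of 5 vacuolar and 4 of 4 calcineurin B-like and SOS2 probe sets lie right of 0, or 3 and 2 against the spike-ins.

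Across the array, 218 of 11989 measurable probe sets were at least 2-fold higher in drought leaves (1.82%, exact binomial interval over probe sets 1.59 to 2.07%) and 307 were at least 2-fold lower (2.56%, 2.29 to 2.86%). Lower probe sets made up 58.5% of the 2-fold differences, and 86.0% (102 higher, 628 lower) against the spike-ins. With G. hirsutum probe sets alone the share was 53.3%, and with no filter on low signals the balance turned, with 3004 higher and 2838 lower (48.6% lower). Of the 200 measurable probe sets with a gene name, 191 lay within 2-fold, 2 were higher and 7 lower. The largest differences among measurable probe sets were 2.98 and -3.11, neither on a probe set with a single named gene. Without probe sets ending in _x_at or assigned to several genes, the largest excess was 2.46. Most 2-fold differences involved a dim signal: in 139 of the 218 higher and 260 of the 307 lower, the smaller signal lay under the 95th percentile of 51 reporter controls on that array (75.7 well watered, 144 drought). These limits differ between the arrays, so the counts of higher and lower cannot be compared with each other. In the brightest of 3 equal signal classes, 11 were higher and 14 lower, against 166 and 220 in the dimmest. Among 810 pairs of probe sets of the same transcript cluster, log2 differences correlated at r = 0.13 across clusters, which are not independent replicates. Where a member of a pair passed 2-fold, both pointed the same way in 49 of 82 pairs (59.8%, exact binomial interval 48.3 to 70.4%).

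The authors' deposited list names 110 probe sets, 88 lower and 22 higher in drought leaves; its rule of choice is not stated. Probe sets with 1 named gene were ACO1, Pat1 and PAP1, all lower. In the authors' deposited list ACO1, an ACC oxidase gene of ethylene synthesis at another locus than the one above, was called present in well-watered leaves (detection p = 0.0239) and absent in drought leaves (p = 0.219), with signals of 98.5 and 13.6. The value table gave 106 and 24.7 (log2 difference -2.10), below the measurable minimum. Pat1 stood at 300.2 and 105 in the authors' deposited list (-1.52, against -1.80 in the value table) and PAP1 at 447 and 197 (-1.18, against -1.21). The loci without a gene name, given here after their values were seen, were LOC107907037, with 381 and 1292 in the authors' deposited list (1.76) and 1.95 in the value table, LOC107946138 (1.27 listed, 1.71 in the table), LOC107889256 (-1.67 and -1.20) and LOC107894267 (-1.12 and -1.03). Other probe sets of these loci gave -0.85 for LOC107894267, at a far brighter 5753 against 3183, and -1.02 for LOC107946138, at a signal below the measurable minimum (18.1 against 8.9). Both have IDs that mark the orientation opposite to the listed probe set, so they may not read the same strand. In the value table LOC107889256 was under 2-fold with the pseudocount, and the listed probe set of LOC107894267 with the pseudocount and with quantile or intensity-dependent centring.

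All 110 listed directions were the same in the value table (100%, exact binomial interval 96.7 to 100%), although 0 of the listed signals equalled the table's on either array. Both sources concern the same 2 samples, so this is not independent evidence of direction. At least 2-fold differences numbered 100 in the authors' deposited list and 85 among the same probe sets in the value table. Of the 88 listed as lower, 56 were called absent and 2 marginal on the drought array. Of the 22 listed as higher, 6 were called absent on the well-watered array. Measurable probe sets past 2-fold but not listed numbered 203 higher and 256 lower.

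**Figure D3:**
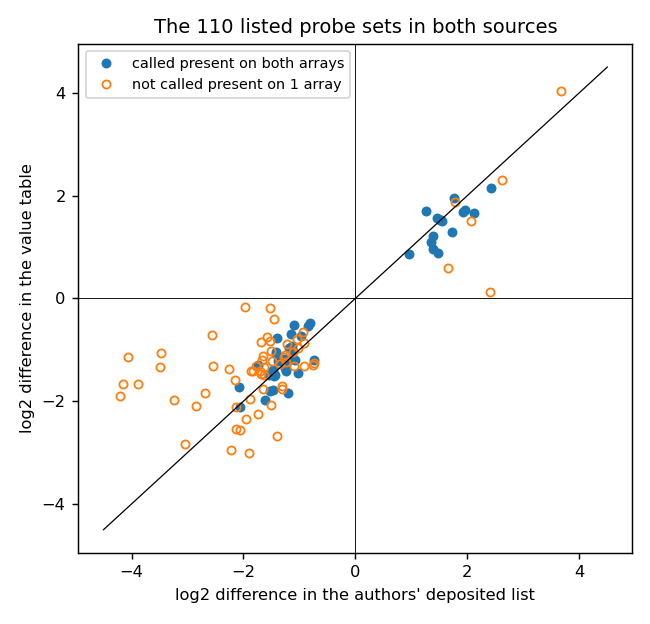
Log2 difference (drought minus well watered) of each of the 110 listed probe sets, in the authors' deposited list on the horizontal axis and in the value table on the vertical axis, with the line of equality. Filled blue points were called present on both arrays (46) and open orange points were not on 1 of them (64). Every point lies in the lower left or upper right quadrant, and open points scatter farther from the line.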

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

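Tests of the deposited list's sizes, of the cre controls and of a deficit added back were chosen after those results were seen; the remaining tests were chosen before, except that the intervals of the G. raimondii values were weighed after their values were known. Of the 52 reporter controls, 1 gave a signal of 13616 on the well-watered and 16611 on the drought array, while the other 51 reached at most 107 and 186. Its signals lay inside the range of the 6 cre spike-in probe sets on each array (12866 to 16778 and 15147 to 19204).

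The hybridisation spike-ins were brighter on the drought array in 27 of 27 probe sets, by a median log2 difference of 0.25 (0.05 to 0.40). These probe sets repeatedly cover only bioB, bioC, bioD and cre, so they are not independent measurements. A scaling difference shared with the plant transcripts would raise plant probe sets of the same signal equally, but the spike-ins exceeded the nearest 200 of these by a median of 0.168, above their robust SD of 0.090. That value combines an excess of 0.254 in the 21 bioB, bioC and bioD probe sets with 0.061 in the 6 brighter cre probe sets, where the plant median was itself 0.17, so that most of the difference was shared and the excess only just passed their spread of 0.053. The same 0.168 met the prediction for less plant cRNA relative to spike-in in the drought hybridisation. That prediction is the scaling comparison read the other way, so the value gives it no separate support. The excess was also unequal, 0.254 against 0.061, and the reason was not tested. A pipetting difference and a lower yield of plant cRNA remain open alike. A response of the leaves to drought is also open, since each treatment has 1 array.

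The median size of the log2 difference was 1.52 in the deposited list and 1.33 for the same probe sets in the value table, and it was larger in the list for 75 of the 110. A single scaling factor between the list and the table is argued against by the scatter of their ratio, with a robust SD of 0.444 on the log2 scale on the drought array and 0.190 on the well-watered array. Where a probe set was not called present on 1 array, the listed difference exceeded the table's by a median of 0.281, against 0.098 where both calls were present. This may reflect selection of the list on its own noisy low signals. A biological explanation was not tested, since both sources concern the same 2 samples.

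Probe sets designed from Gossypium raimondii, a diploid relative, made up 43 of the 88 listed decreases (48.9%, exact binomial interval 38.1 to 59.8%), 4 of the 22 listed increases and 17.3% of measurable probe sets. These sets are unlike, since only 68 of the 88 listed decreases were measurable. A general deficit of such probe sets was seen: their median differed from that of signal-matched G. hirsutum probe sets by -0.082 (95% interval -0.112 to -0.051). This was short of the 0.1 set in advance by more than its resampling SD of 0.016. The interval holds 0.1, however, so that limit alone does not decide. A uniform deficit is argued against as the whole cause by a further test. For this, 0.112, the largest deficit in the interval, was added back to every measurable G. raimondii probe set. Decreases of 2-fold were still 1.791 times as frequent as in matched G. hirsutum probe sets (1.47 to 2.16), or 1.51 times outside the list (1.2 to 1.87). The intervals of these ratios, here and below, hold the G. hirsutum share fixed and so are too narrow. Larger scatter in both directions together with a deficit stays open. Outside the list 2-fold increases were 1.215 times as frequent (0.928 to 1.56), under the 1.5 set in advance, but that limit made no allowance for a deficit. With the estimate of 0.082 added back they were 1.56 times as frequent (1.24 to 1.95), and with 0.112 added back 1.67 times (1.33 to 2.06). A drought response of the transcripts these probe sets detect could also underlie the excess and was not tested.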

How the results depend on the processing

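The scaling to spike-ins and both reporter filters were chosen after seeing the data. Counts of 2-fold differences, 218 higher and 307 lower, depended on the treatment of dim signals. They were 3004 and 2838 with no filter, 24 and 43 above the 75th percentile, 83 and 153 with both arrays above the minimum, 110 and 178 with the pseudocount, and 93 and 163 above the mean signal of all dim reporters. Above the dim reporters on at least 1 array, 81 were higher, and the 399 lower stayed within 1.5 times. Without shared-probe types (_x_at and _s_at) they were 106 and 129, and 177 were lower with G. hirsutum probe sets alone. Thresholds of 1.5-fold and 3-fold gave 878 and 1086, and 31 and 51. These filters and thresholds change how many probe sets qualify by construction. Scaling to the spike-ins gave 102 and 628 and moved the transcription factor median to -0.24, by subtracting 0.25 from every difference. Centring, quantile and lowess scaling left both counts within 1.5 times. Directions in the deposited list were the same under every alternative except spike-in scaling, where 99.1% were. Of all alternative values of these counts, the listed directions and the transcription factor median, 21 moved past their bounds and 30 did not. Of those of single probe sets and families, 5 moved by more than their spread and 529 did not, but centring on the median and spike-in scaling shift each probe set by 1 amount smaller than that spread, so they could not move a single probe set past it. The pseudocount brought MPK3 to 0.86, MAPKKK to -0.98, FLA14 to 0.99 and FLA6 to -0.81, all under 2-fold. The 75th-percentile filter left too few transcription factors for a median, and filters leave a single gene's value as it is. No paired analysis was possible because each treatment has 1 array. Signal over background limits the dim genes.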

Other observations

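Bright named genes, picked by signal after the values were seen, stayed under 2-fold. Of 55 named probe sets with a mean signal of at least 1000, 0 reached 2-fold, and the largest difference was that of the histone gene HIS2B, at 2662 in well-watered and 4236 in drought leaves (0.67). Another histone gene, HIS3, measured 4400 and 5753 (0.39), and HrBP1 measured 4004 and 5295 (0.40). On the other side, DFR had the largest deficit (-0.48), and CPR2 measured 1600 and 1189 (-0.43). The HIS2B probe set ends in _x_at and can detect related copies. Besides RCA1 and CAT2, the brightest named genes were CBP2 at 14718 and 18046 (0.29) and CBP3 at 12628 and 13957 (0.14), the latter lower under quantile normalization and against the spike-ins.

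The 4 probe sets designed from ribosomal RNA gave 0.56, -0.12, 0.37 and -1.32. Of the 51 dim reporter controls, 36 were higher on the drought array, with a median log2 difference of 0.70 at median signals of 11.4 and 15.6.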
